A study of Rattus norvegicus with 30 samples.

How the data were processed

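Total RNA from rat hippocampus was measured on Affymetrix arrays, with 59 probe sets that are array controls. The deposited table holds 1 signal intensity per probe set and array on a linear scale. How the intensity values were computed from the images is not given in the sources used here. As deposited, the trimmed means of the arrays, leaving out 2% at each end, lay between 150.1 and 150.2, so the arrays had already been brought to a common level. Groups follow the labels, kainate or PBS at 1, 6, 24, 72 or 240 h, with 3 arrays in each of 10 groups and 30 arrays in all. The labels number the replicates but do not say more about how the animals were assigned, so p-values measure the spread between these arrays. Arrays have no read depth, and their number limits the precision.

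Each array was scaled to the common trimmed mean, and values were floored at the 20th percentile of all values, a signal of 10.95 (log2 3.45), and turned into log2. A probe set was tested when it lay above the 40th percentile, a signal of 35.2, on at least 3 of 30 arrays, which kept 6305 probe sets and 3702 genes. Array controls were left out of the tests. A fold against a group with all arrays at the floor is given as a lower bound.

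Gene names came from the platform annotation provided with the reference files, matched through gene identifiers. Of 8740 probe sets that are not controls, 7006 had 1 gene, 308 had several and 1426 had none, and 6994 matched a current gene identifier. These stand for 4736 genes, and no gene was named from a probe set with several. Where a gene had more than 1 probe set, the one with the highest mean log2 value stood for it. The others did not always pass with it, here and for some further named genes. At 24 h 1 of 3 tested probe sets passed for Gria1, Slc1a1, Hspa9 and Mcm6. It was 1 of 2 for Nr4a3, Nptx2, Gabra5, Atp2b4, Igfbp5 and Cacnb2, and 2 of 5 for Ccnd1. Of Bdnf 2 of 7 passed at 1 h and 5 of 7 at 6 h.

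The tests were made with limma 3.58.1 in R 4.3.3: a model with a mean for each group over all 30 arrays, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment with a threshold of 0.05. The residual degrees of freedom were 20 and the prior degrees of freedom 7.27. Contrasts gave the kainate effect at each time, its mean over times, F tests for an effect at any time and for differences between times, and the F test for differences among controls. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

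The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. At each time the rule names the 8 genes with the largest rise and the 8 with the largest fall that passed and whose groups do not overlap, and from each list the 2 passing members with the largest change. Where fewer than 4 genes pass, the 4 with the smallest adjusted p are named as not passing where they do not pass. For tests over all times it names the 10 genes with the smallest p.

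The 23 gene lists were tested at each of 5 times, 115 tests in all, with camera at an inter-gene correlation of 0.01, and 33 passed. With an estimated correlation 20 passed, all 20 of them among the 33. Some genes are on several lists, so the list calls are not independent of each other. The other list settings were fry, a test without comparison to other genes (38 passed, 30 of the 33 among them), quantile normalization and the mean of all probe sets of a gene. The lists were immediate early transcription factors, activity-regulated effector genes, neuropeptides and growth factors, cytokines, chemokines and acute inflammation, complement and antigen presentation, microglia and macrophage markers, reactive astrocyte genes, astrocyte markers, oligodendrocyte and myelin genes, neuron markers, interneuron markers, blood and endothelial markers, choroid plexus and neighbouring region markers, glutamate receptors and transporters, GABA receptors, synthesis and transport, voltage-gated and inward-rectifier ion channels, heat shock and endoplasmic reticulum stress, oxidative stress and metallothioneins, extracellular matrix and tissue remodelling, glucocorticoid-responsive genes, cholesterol synthesis, cell cycle, and cell death regulators.

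The procedure was tested on simulated data of 6305 probe sets with 200 changed. In the first setting, called pooled, the spread of each probe set was pooled over times and scaled by 1 factor per time. Changes of log2 1 were then recovered at 52.2% (1 h), 55.2% (6 h), 59.7% (24 h), 58.2% (72 h) and 59.7% (240 h). False calls made up 14.8% of calls at 1 h, 0% at 6 h, 12.4% at 24 h, 0.952% at 72 h and 9.48% at 240 h. At 1, 24 and 240 h this is more than the threshold of 0.05 promises. Each share comes from a single simulated data set. With a spread of its own for each probe set and time, false calls made up 44.0% at 1 h, 12.8% at 6 h, 33.1% at 24 h, 4.81% at 72 h and 32.4% at 240 h, more than the threshold of 0.05 promises at each time except 72 h. The median residual SD per time was 0.34, 0.23, 0.30, 0.20 and 0.30, and that of the shared spread was 0.31, which the median of 1 h exceeded. Each value per time rests on 6 arrays and the shared one on 30. A median SD from fewer arrays tends to be lower, so those of 24 and 240 h cannot be ranked against the shared one. In a simulation without any change, 0 probe sets were called at any time with the pooled spread. With a spread of its own for each probe set and time, 37 were called at 1 h, 7 at 6 h, 26 at 24 h and 4 each at 72 and 240 h, more at 72 and 240 h than the 3 called there in the real data. Such a spread is estimated from the few arrays of a time and varies more than the true one. It can therefore overstate the false calls.

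The alternatives were quantile normalization, no scaling, floors at the 5th and 40th percentile, no filter or a stricter filter at the 60th percentile, no intensity trend, array weights, the replicate number as a block, the 6 arrays of a time alone, and leaving out each array in turn. Fits with the arrays of 6 and 72 h alone, and with those of 1, 24 and 240 h alone, were added after the data were seen. So were regroupings within these 2 sets of arrays. The hexokinase ratio and the spike-in transcripts were also added then to the measures of RNA quality and array level.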

Results

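Gene expression was measured in rat hippocampus on 30 Affymetrix arrays. Per the labels, the rats had been treated with kainate or with phosphate-buffered saline (PBS) and were killed 1, 6, 24, 72 or 240 h later. Kainate is an agonist of glutamate receptors that causes seizures, and the title of the series names seizures. The design has 10 groups of 3 arrays, a kainate and a PBS control group at each time. The trimmed mean signal of the arrays lay between 150.1 and 150.2 as deposited. Replicate arrays of a group correlated with a median r of 0.947 across probe sets, and the lowest r of any pair of arrays was 0.885. The number of arrays limits the precision of every value given here.

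The first principal component, with 16.2% of the variance, separated the arrays of 6 and 72 h from those of 1, 24 and 240 h, in kainate and control groups alike. The median correlation was 0.954 among the arrays of 6 and 72 h, 0.927 among those of 1, 24 and 240 h and 0.925 between the 2 sets. The 3 prime to 5 prime log2 ratio of beta-actin was 0.44 ± 0.10 (SD) on the 12 arrays of 6 and 72 h and 0.68 ± 0.15 on the other 18, and that of hexokinase 0.97 ± 0.24 and 1.40 ± 0.32. Each kainate group is compared with the controls of its own time, which lie in the same set of arrays.

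**Figure D1:**
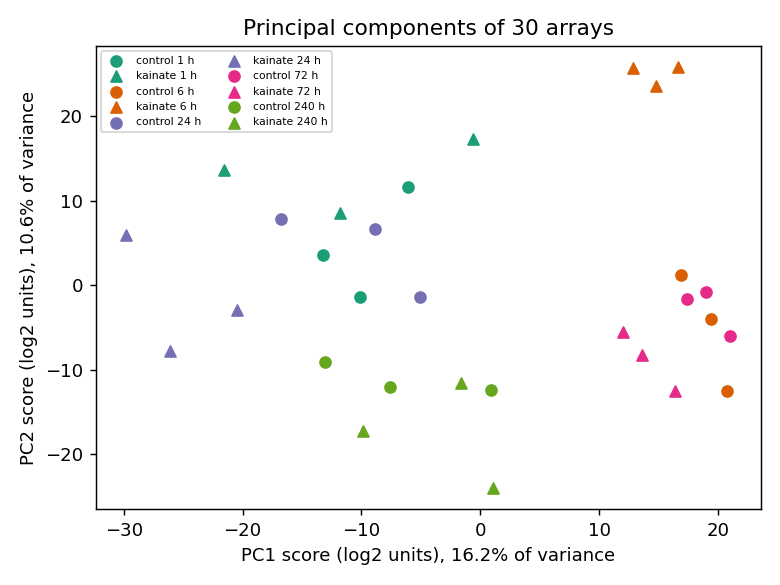
Scores of the 30 arrays on the first 2 principal components of the log2 signals (PC1 on the x axis, PC2 on the y axis, log2 units), with colour for the time, circles for controls and triangles for kainate. The 12 arrays of 6 and 72 h sit to the right of the 18 arrays of 1, 24 and 240 h along PC1, which holds 16.2% of the variance.

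Signs of RNA quality and array level were compared between kainate and control arrays by an exact permutation test within times, two-sided. The 3 prime to 5 prime ratios speak to RNA quality, and the array median and spike-in transcripts to array level. The 3 prime to 5 prime log2 ratio of Gapdh differed by 0.02 (exact p = 0.564) and that of beta-actin by 0.06 (exact p = 0.238). The log2 median of the arrays differed by −0.03 (exact p = 0.303). Of 3 further measures chosen after the data were seen, the hexokinase ratio differed by 0.06 (exact p = 0.628) and the spike-in transcript BioC by 0.11 (exact p = 0.212). The spike-in transcript CreX was higher by 0.24 on the kainate arrays (exact p = 0.00975, adjusted over the 6 measures 0.0585). Within a single time the exact test of 3 against 3 arrays cannot give a p under 0.1. At that smallest exact p of 0.1 were the Gapdh ratio, higher by 0.08 at 6 h and lower at 72 h (−0.12), the array median at 6 h (−0.10), CreX at 6 h (0.18) and 24 h (0.41), and BioC at 72 h (0.29).

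At 1 h after kainate transcription factors of the immediate early response were among the largest rises. Egr2, a zinc finger factor induced by neuronal activity, rose 10.2-fold (log2 change 3.35 ± 0.31 SE, n = 3 arrays per group, limma adjusted p = 2.62e-08). Its signal was 47.1 ± 21.1 (SD) in controls and 453 ± 55.5 after kainate. Dusp1, a phosphatase that switches off MAP kinases, rose 8.37-fold and the orphan nuclear receptor Nr4a1 8.34-fold. Junb and Fos, subunits of the AP-1 transcription factor, rose 7.15-fold and 4.59-fold. Arc, a synaptic protein translated near active synapses, rose 4.31-fold, from 461 ± 110 to 1954 ± 37.8 (SD, n = 3).

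In total 69 of 6305 tested probe sets differed at 1 h, 57 higher and 12 lower, with 610 at an unadjusted p under 0.05. They include 23 genes higher and 5 lower. Groups did not overlap at 10.2% of probe sets, where chance gives 10%. Of the immediate early transcription factors, 9 of 19 measured members rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 8.43e-31). Nr4a2, another orphan nuclear receptor, rose 3.89-fold. Of the activity-regulated effector genes 5 of 18 rose, or 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.15e-17). Of the glucocorticoid-responsive genes 2 of 9 rose, Dusp1 and Errfi1, a feedback inhibitor of the EGF receptor, which rose 2.50-fold, or 3 adjusted over the list alone (camera adjusted p = 0.000349). Neuropeptides and growth factors had 2 of 20 members higher, or 4 adjusted over the list alone (camera adjusted p = 0.0134), but adjusted p = 0.113 with an estimated correlation. These 2 were Bdnf, a neurotrophin, 2.21-fold, and Crh, the stress peptide corticotropin-releasing hormone, 2.27-fold. The list call was also lost without kainate replicate 3 of 1 h (adjusted p = 0.398) and without control replicate 2 of 1 h (adjusted p = 0.123). Ccn1, a secreted matrix protein, rose 4.39-fold against controls of which 2 of 3 lay at the floor, and Plat, tissue plasminogen activator, rose 1.77-fold.

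The named falls at 1 h had smaller changes than the largest rises, and those other than Ndst1 had less support. Ndst1, an enzyme of heparan sulfate synthesis, was 3.73-fold lower and Acadm, a mitochondrial acyl-CoA dehydrogenase, 3.10-fold lower, with 1 of 3 kainate arrays at the floor. Col5a1, a collagen chain, Tap1, a peptide transporter of antigen presentation, and Sfxn1 had log2 changes of −0.98, −0.67 and −0.49. Fitted with only the 6 arrays of 1 h, 31 probe sets passed, all 31 higher, so that none of the falls passed, and with the arrays of 1, 24 and 240 h alone 43 passed. Of the 17 named genes, 11 passed in all 6 fits that left out an array of 1 h, and Acadm, Col5a1, Crh, Plat, Sfxn1 and Tap1 did not. Without kainate replicate 3 of 1 h 96 probe sets passed, 52 higher and 44 lower.

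At 6 h the response was wider and inflammatory genes were among the highest. Ccl2, a chemokine that attracts monocytes, rose 34.5-fold (log2 change 5.11 ± 0.43 SE, n = 3 arrays per group, limma adjusted p = 1.54e-09), from 29.7 ± 4.72 to 1016 ± 25.5 (SD). Socs3, an inhibitor of cytokine signalling, rose 7.99-fold and Ptgs2, the inducible cyclooxygenase, 8.19-fold. Dusp1 rose 10.6-fold, Bdnf 8.27-fold, Errfi1 8.20-fold, Junb 7.92-fold and Fos 5.84-fold. Ccn1 rose at least 8.14-fold, since all 3 controls lay at the floor.

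At this time 249 probe sets differed, 204 higher and 45 lower, with 925 at an unadjusted p under 0.05, and groups did not overlap at 27.7% of probe sets, where chance gives 10%. The median log2 change of all tested probe sets was −0.11, or −0.06 with quantile normalization. Of the activity-regulated effector genes 14 of 18 rose, 15 adjusted over the list alone (camera adjusted p = 5.56e-40), and of the immediate early transcription factors 14 of 19 rose, 17 adjusted over the list alone (camera adjusted p = 9.65e-33). Cytokines, chemokines and acute inflammation genes had 7 of 18 higher, 8 adjusted over the list alone (camera adjusted p = 2.59e-09). Among the 9 of 20 neuropeptides and growth factors that rose, 11 adjusted over the list alone (camera adjusted p = 4.52e-12), were Bdnf and Scg2, a secretory granule protein, 3.24-fold. Glucocorticoid-responsive genes rose in 5 of 9 cases, 5 adjusted over the list alone (camera adjusted p = 6.58e-09).

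Matrix, glial and interneuron genes moved at 6 h as well. Extracellular matrix and tissue remodelling genes had 6 of 29 higher, 7 adjusted over the list alone (camera adjusted p = 6.12e-06), among them Mmp9, a gelatinase, 5.74-fold with 1 of 3 controls at the floor and Plaur, the urokinase receptor, 4.42-fold. Of the reactive astrocyte genes 4 of 15 rose, 5 adjusted over the list alone (camera adjusted p = 1.76e-05), including Socs3 and Cd44, a hyaluronan receptor, 3.52-fold. The interneuron markers had 5 of 17 higher, 6 adjusted over the list alone (camera adjusted p = 0.00141). Penk and Tac1, precursors of enkephalins and of substance P, rose 2.69-fold and 2.46-fold. Both also count among the neuropeptides and growth factors. Heat shock and endoplasmic reticulum stress genes had 2 of 19 higher, 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00246), but adjusted p = 0.142 with an estimated correlation. The 2 were the chaperones Hspa5, 1.66-fold, and Hsph1, 1.58-fold. Of lists that did not pass, Slc2a1, the glucose transporter of the blood-brain barrier, rose 2.42-fold, Hmox1, heme oxygenase, 2.25-fold, Idi1 and Insig1 of sterol metabolism 2.23-fold and 1.77-fold, Lgals3, a galectin of activated macrophages, by 1.58 on the log2 scale, and C1qb, a complement chain made by microglia, 2.29-fold. Txnrd1, thioredoxin reductase, and Kcnk1, a potassium channel, rose 1.62-fold and 1.40-fold.

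Among the falls at 6 h were Dbp, a transcription factor of circadian output, 2.54-fold lower (adjusted p = 0.000583), and Myo5b, a myosin motor, 2.05-fold lower (adjusted p = 0.000293). Sds, serine dehydratase, was 4.68-fold lower, with 2 of 3 kainate arrays at the floor, Apoc1, an apolipoprotein, 2.61-fold lower, with 1 of 3, Cgrrf1 2.11-fold lower and the kinase Sgk2 2.05-fold lower. Efemp1 and Pgf were each at least 2.92-fold lower, with all 3 kainate arrays at the floor. Of the 33 named genes, 22 passed in all 6 fits without an array of 6 h, and Apoc1, Cgrrf1, Efemp1, Hsph1, Insig1, Kcnk1, Lgals3, Pgf, Sds, Sgk2 and Txnrd1 did not. Without kainate replicate 3 of 6 h, 163 probe sets passed, and 161 of these were among the 249. With array weights 633 passed, 361 higher and 272 lower, and with the arrays of 6 and 72 h alone 481, 300 higher and 181 lower.

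At 24 h none of the 19 immediate early transcription factors passed as higher, and genes of activated microglia, reactive astrocytes, antigen presentation and matrix had risen. Lgals3 was 21.1-fold higher (log2 change 4.40 ± 0.36 SE, n = 3 arrays per group, limma adjusted p = 1.26e-09), with 2 of 3 controls at the floor and a kainate signal of 263 ± 13.7 (SD). Vim, an intermediate filament of reactive astrocytes, rose 5.85-fold, from 197 ± 10.5 to 1159 ± 134 (SD, n = 3). Spp1, osteopontin, rose 8.35-fold, the calcium-binding proteins S100a4 and S100a10 7.59-fold and 5.41-fold, and H19, a non-coding RNA, 14.2-fold. Of Spp1 and H19 1 of 3 controls lay at the floor. Neuronal genes fell: Camk2a, a kinase of synaptic plasticity, was 3.72-fold lower and Ppp3ca, the catalytic subunit of calcineurin, 1.96-fold lower, from 1755 ± 127 to 899 ± 138 (SD, n = 3). Of Camk2a 1 of 3 kainate arrays lay at the floor, and another of its probe sets, with a log2 change of 0.50, did not pass.

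In all, 713 probe sets differed at 24 h, 317 higher and 396 lower, with 1669 at an unadjusted p under 0.05, and groups did not overlap at 28.1% of probe sets, where chance gives 10%. Microglia and macrophage markers had 6 of 14 higher, 7 adjusted over the list alone (camera adjusted p = 2.62e-07). Reactive astrocyte genes had 6 of 15 higher, 6 adjusted over the list alone (camera adjusted p = 3.52e-05), among them Timp1, an inhibitor of metalloproteinases, 3.74-fold. Of the genes of complement and antigen presentation 6 of 15 rose, 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.76e-05), including RT1-Da, a class II histocompatibility chain, 4.38-fold, and Psmb8, an immunoproteasome subunit, 4.33-fold. Extracellular matrix and tissue remodelling genes had 8 of 29 higher and 1 lower, 10 and 2 adjusted over the list alone (camera adjusted p = 0.000412), with Mmp9 4.96-fold higher. Cytokines, chemokines and acute inflammation genes had 3 of 18 higher, 6 adjusted over the list alone (camera adjusted p = 0.00677), but adjusted p = 0.0649 with an estimated correlation. Ccl2 was 2.84-fold higher and Stat3, a cytokine-activated transcription factor, 2.28-fold, with 1 of 3 controls at the floor. Cyba, a subunit of the phagocyte NADPH oxidase, and Crhbp, which binds corticotropin-releasing hormone, rose 5.27-fold and 5.55-fold, the latter with 1 of 3 controls at the floor.

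Neuron markers fell at 24 h in 7 of 20 cases, 8 adjusted over the list alone (camera adjusted p = 0.000124), and beside them the microglia list had a median log2 change of 0.67 and the neuron list −0.37. Cholesterol synthesis genes fell in 3 of 14 cases, 3 adjusted over the list alone (camera adjusted p = 0.00663), with Idi1 1.78-fold and Sqle, squalene epoxidase, 1.67-fold lower. Neuropeptides and growth factors had 6 of 20 higher and 2 lower, 7 and 3 adjusted over the list alone (camera adjusted p = 0.0122), but adjusted p = 0.106 with an estimated correlation. Vgf and Trh, precursors of secreted peptides, rose 2.89-fold and 2.67-fold. Heat shock and endoplasmic reticulum stress genes had 4 of 19 higher, 5 adjusted over the list alone (camera adjusted p = 0.0267), but adjusted p = 0.338 with an estimated correlation. Hspa9, a mitochondrial chaperone, and Cryab, a small heat shock protein, were 2.15-fold and 1.67-fold higher. Hspb1, on this list and among the reactive astrocyte genes, counted as not passing by the probe set that stands for it. Its other probe sets rose, as given under the other observations. The heat shock call was also lost without control replicate 3 of 24 h (adjusted p = 0.125) and without kainate replicate 1 of 24 h (adjusted p = 0.0513). Voltage-gated and inward-rectifier ion channels had 7 of 35 lower and 1 higher, 8 and 1 adjusted over the list alone, without passing as a list (camera adjusted p = 0.0598). Kcnq3, a potassium channel, and Cacnb2, a calcium channel subunit, were 1.96-fold and 2.06-fold lower.

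Several lists did not pass at 24 h although single members did. Activity-regulated effector genes had 5 of 18 higher and 3 lower, 7 and 4 adjusted over the list alone (camera adjusted p = 0.0744), and interneuron markers 3 of 17 higher and 2 lower, 3 and 3 adjusted over the list alone (camera adjusted p = 0.580). Immediate early transcription factors had 4 of 19 lower, 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.205). Glutamate receptors and transporters had 3 of 21 lower, 3 adjusted over the list alone (camera adjusted p = 0.569), with a median log2 change of 0.01 and a mean of −0.11. They include Gria1, an AMPA receptor subunit, 1.93-fold lower, and the transporter Slc1a1, 1.51-fold lower. Of each of these genes 1 of 3 tested probe sets passed, and none passed as higher. GABA receptors, synthesis and transport had 1 of 19 lower, 1 adjusted over the list alone (camera adjusted p = 0.482), which was Gabra5, 1.56-fold lower. Astrocyte markers had 2 of 13 lower, 3 adjusted over the list alone (camera adjusted p = 0.205), the glycolytic enzyme Aldoc and S100b, 1.77-fold and 1.49-fold lower. Cell cycle genes had 4 of 13 higher and 1 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.106), with cyclin D1, Ccnd1, 2.22-fold higher and Mcm6, whose groups overlap, 2.03-fold. Blood and endothelial markers had 1 of 13 higher and 2 lower, 1 and 2 adjusted over the list alone (camera adjusted p = 0.757), the falls being Slco1a4 and Slc4a1, 2.04-fold and 1.75-fold. Cell death regulators had 1 of 15 lower, Bcl2, which blocks apoptosis, 1.58-fold, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.759). Choroid plexus and neighbouring region markers had 1 of 9 higher, Igfbp2, which binds insulin-like growth factors, 2.37-fold, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.799), with a median log2 change of −0.06 and a mean of 0.12. Of the oligodendrocyte and myelin genes Gjb1, a gap junction protein, was 2.06-fold lower, of the oxidative stress genes Gpx1, glutathione peroxidase, was 2.42-fold higher, and of the glucocorticoid-responsive genes Nfkbia, an inhibitor of NF-kappaB, was 1.64-fold higher.

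Nr4a3 and Nr4a1 were 2.14-fold and 1.89-fold lower at 24 h. Among the strongest falls were also Ces1dl1, a carboxylesterase, 3.92-fold, the calcium pump Atp2b4, 3.81-fold, Igfbp5, 3.32-fold, Odf4, 3.02-fold, Or4c52, an olfactory receptor, 2.86-fold, and the insulin receptor Insr, 2.81-fold. Of Odf4 2 of 3 kainate arrays lay at the floor, and of Atp2b4 and Igfbp5 1 of 3. Acadsb was at least 4.19-fold lower, with all 3 kainate arrays at the floor. The excess of falls over rises was lost or reversed in some fits. Without kainate replicate 3 of 24 h 338 probe sets passed, 170 higher and 168 lower, without control replicate 3 of 24 h 431, 228 higher and 203 lower, and without control replicate 2 of 24 h 482, 241 in each direction. With the 6 arrays of 24 h alone 256 passed, 143 higher and 113 lower, of which 243 were among the 713, with those of 1, 24 and 240 h alone 343, 173 higher and 170 lower, and without the filter 680, 345 higher and 335 lower. The larger count at 24 h than at 6 h was also reversed in some fits. At 6 h 274 passed with its own 6 arrays and 481 with the arrays of 6 and 72 h alone. With array weights 633 passed at 6 h and 543 at 24 h. Of the 50 named genes, 29 passed in all 6 fits without an array of 24 h. The others were Acadsb, Bcl2, Cacnb2, Ccl2, Gabra5, Gjb1, Hspa9, Idi1, Igfbp5, Insr, Kcnq3, Mcm6, Nfkbia, Nr4a1, Odf4, Or4c52, S100b, Slc1a1, Slc4a1, Slco1a4 and Stat3.

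**Figure D2:**
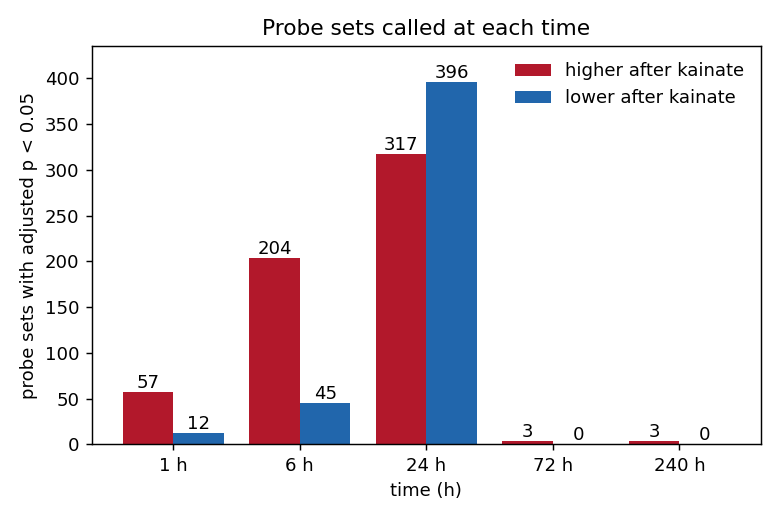
Number of probe sets with a limma adjusted p under 0.05 at each time (x axis, h), higher after kainate in red and lower in blue. The counts were 57 and 12 at 1 h, 204 and 45 at 6 h, 317 and 396 at 24 h, and 3 and 0 at 72 and 240 h.

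At 72 h 3 probe sets differed, all 3 higher, with 399 at an unadjusted p under 0.05, and groups did not overlap at 22.3% of probe sets, where chance gives 10%. S100a4 rose 2.74-fold (log2 change 1.45 ± 0.28 SE, n = 3 arrays per group, limma adjusted p = 0.0461), from 36.1 ± 11.6 to 100.1 ± 38.9 (SD). B4galt6, a glycosyltransferase of lactosylceramide synthesis, rose 1.63-fold (limma adjusted p = 0.0473). Neither passed in all 6 fits without an array of 72 h, which gave 0 or 1 probe sets each. Masp1, a complement protease, with a log2 change of 0.71, and Prdx6, a peroxiredoxin, with 0.57, did not pass (limma adjusted p = 0.0866 for each). With the 6 arrays of 72 h alone 0 probe sets passed in limma, with 944 at an unadjusted p under 0.05, and with array weights 151 passed. Without the intensity trend and with the replicate number as a block 0 passed, with 370 and 410 at an unadjusted p under 0.05. Without the filter 10 passed, all 10 higher, and with the floor at the 40th percentile 7, 6 higher and 1 lower. In a simulation without any change, in which each probe set had its own spread at each time, 4 probe sets passed at 72 h, more than the 3 found. With the spread pooled over times and scaled for each time 0 passed.

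Over all probe sets 0 list members passed at 72 h by limma, but 8 lists shifted as groups. Oligodendrocyte and myelin genes were lower as a list, with 2 of 13 lower adjusted over the list alone (camera adjusted p = 4.76e-05). Microglia and macrophage markers were higher, with 0 of 14 adjusted over the list alone (camera adjusted p = 0.0134, and 0.0609 without kainate replicate 1 of 72 h). The other 6 list calls were lost with an estimated correlation. Heat shock and endoplasmic reticulum stress genes were higher, 4 of 19 adjusted over the list alone (camera adjusted p = 0.000217, adjusted p = 0.0805 with an estimated correlation). Complement and antigen presentation genes were higher, 0 of 15 adjusted over the list alone (camera adjusted p = 0.00248, adjusted p = 0.0506 with an estimated correlation). Oxidative stress and metallothionein genes were higher, 3 of 19 adjusted over the list alone (camera adjusted p = 0.00741, adjusted p = 0.0506 with an estimated correlation). Ion channels were lower, 0 of 35 adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.302 with an estimated correlation). Cytokines, chemokines and acute inflammation genes were higher, 0 of 18 adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.118 with an estimated correlation). Glucocorticoid-responsive genes were lower, 0 of 9 adjusted over the list alone (camera adjusted p = 0.0349, adjusted p = 0.0649 with an estimated correlation). Without kainate replicate 3 of 72 h the ion channel (adjusted p = 0.181), oxidative stress (0.0586), cytokine (0.0670) and glucocorticoid (0.0586) calls were lost. The cytokine call was also lost without control replicate 1 (0.0565) or 2 (0.0520) and the glucocorticoid call without control replicate 1 (0.106) or kainate replicate 1 (0.0609).

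At 240 h 3 probe sets differed, all 3 higher, with 770 at an unadjusted p under 0.05, and groups did not overlap at 14.5% of probe sets, where chance gives 10%. Pola2, a subunit of DNA polymerase alpha, rose 3.96-fold (limma adjusted p = 0.00622), against controls of which 2 of 3 lay at the floor. Hbegf, a growth factor that binds the EGF receptor, rose 3.59-fold (log2 change 1.84 ± 0.34 SE, n = 3 arrays per group, limma adjusted p = 0.0241), from 15.7 ± 5.91 to 54.2 ± 7.27 (SD). Lin7a, a synaptic scaffold protein, with a log2 change of 1.18, and Pde4d, a phosphodiesterase, with −1.60, did not pass (limma adjusted p = 0.0693 for each). With the 6 arrays of 240 h alone 0 probe sets passed in limma, with 475 at an unadjusted p under 0.05. Without kainate replicate 1 of 240 h 19 passed, 4 higher and 15 lower, without replicate 2 0, with 691 at an unadjusted p under 0.05, and without replicate 3 8, 4 in each direction. Without control replicate 2 of 240 h 6 passed, all 6 higher. Without the filter 13 passed, 12 higher and 1 lower. Neither named gene passed in all 6 fits without an array of 240 h: Hbegf was lost without control replicate 1 (adjusted p = 0.263), control replicate 3 (0.0718) or kainate replicate 2 (0.126), and Pola2 without kainate replicate 2 (0.0726). With the arrays of 1, 24 and 240 h alone 0 passed, with 510 at an unadjusted p under 0.05, with either other floor 1, and with the stricter filter 0, with 553 at an unadjusted p under 0.05, where 1 of the 3 was still tested. In the simulation without any change 4 probe sets passed at 240 h as well, again more than the 3 found, and 0 with the pooled spread.

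Neuron markers were lower as a list at 240 h, with 0 of 20 adjusted over the list alone (camera adjusted p = 0.0126), adjusted p = 0.113 with quantile normalization and 0.0546 without kainate replicate 1 of 240 h. Reactive astrocyte genes were higher, 0 of 15 adjusted over the list alone (camera adjusted p = 0.0273, adjusted p = 0.0506 with an estimated correlation). Extracellular matrix and tissue remodelling genes were higher, 2 of 29 adjusted over the list alone (camera adjusted p = 0.0467, adjusted p = 0.118 with an estimated correlation). The reactive astrocyte call was lost without kainate replicate 2 of 240 h (adjusted p = 0.143). The matrix call was lost without kainate replicate 1, 2 or 3 (adjusted p = 0.0546, 0.117 and 0.0631) and without control replicate 3 (0.151).

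**Figure D3:**
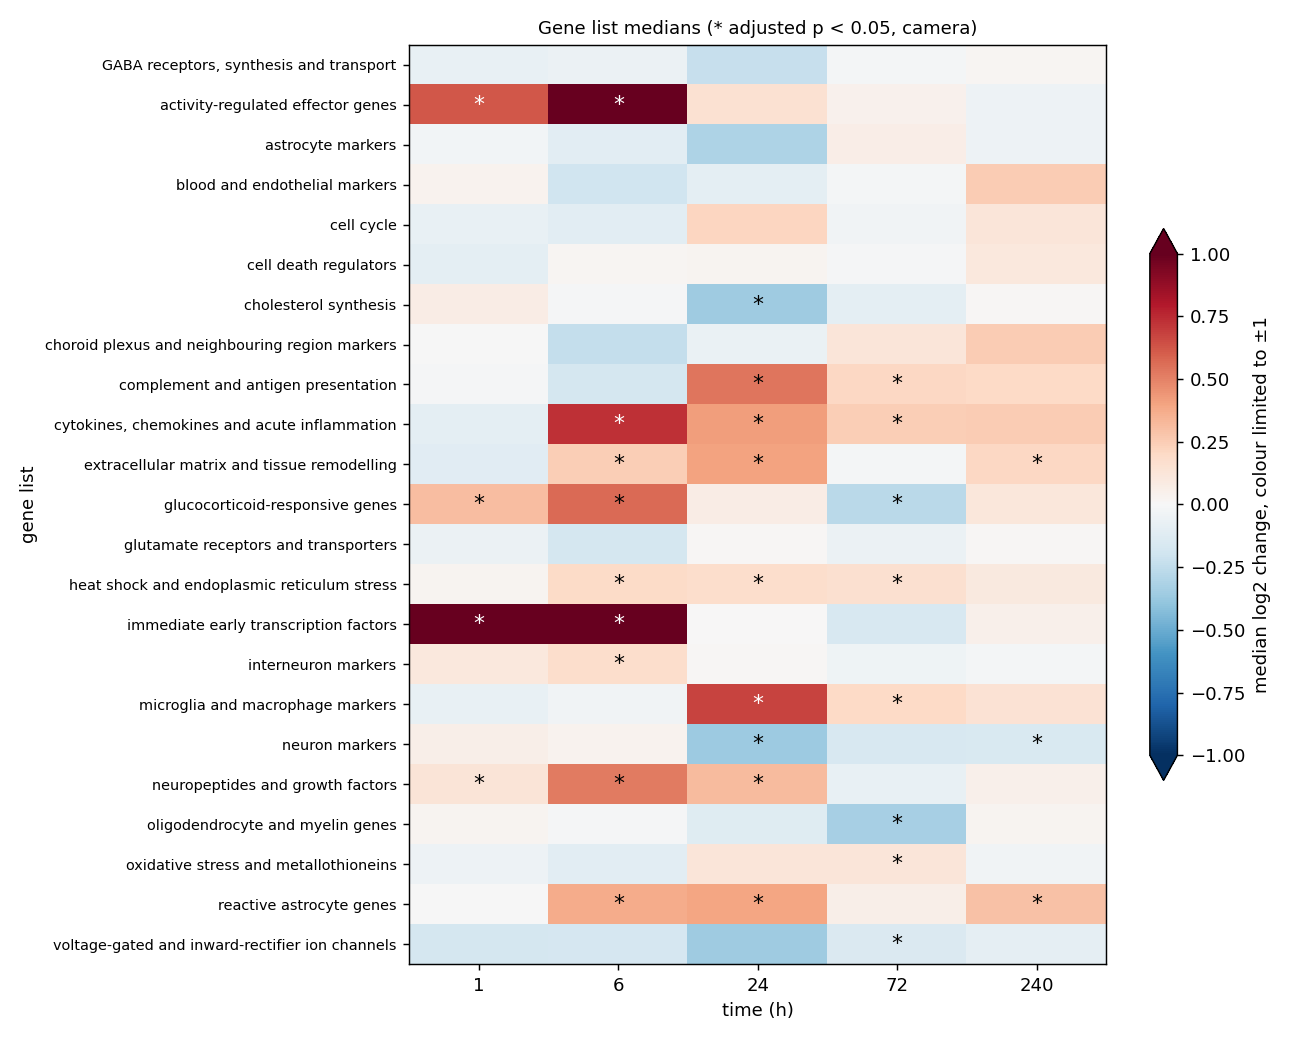
Median log2 change after kainate of each of the 23 gene lists (y axis) at each time (x axis, h), red for higher and blue for lower, with colour limited to a change of 1 in either direction and an asterisk where the camera adjusted p is under 0.05. Immediate early transcription factors and effector genes rose at 1 and 6 h, and microglia markers rose and neuron markers fell at 24 h.

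Across the 5 times the kainate effect was tested for any change and for differences between times. In the limma F test for an effect at any time 588 probe sets passed, and 418 differed between times. The 10 genes with the smallest p for any effect were Nptx2, a neuronal pentraxin, Bdnf, Arc, Fos, Errfi1, Nr4a1, Vgf, Nr4a3, Lgals3 and Egr2. For differences between times they were Arc, Nptx2, Errfi1, Nr4a3, Nr4a1, Fos, Bdnf, Egr1, Egr2 and Cebpb. Nptx2 had log2 changes of 1.05, 2.77 and 1.32 at 1, 6 and 24 h. Cebpb, a transcription factor of the acute phase response, had 1.04 and 2.56 at 1 and 6 h and −0.39 at 24 h, where it did not pass. Averaged over times, 278 probe sets passed, 187 higher and 91 lower. With array weights the effect at any time had 923. With the arrays of 1, 24 and 240 h alone the mean effect had 50, the effect at any time 187 and the differences between times 119, and with the arrays of 6 and 72 h alone the effect at any time had 362.

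Effects at 24 h differed from those at 6 h at 332 probe sets, from those at 1 h at 238, from those at 240 h at 355 and from those at 72 h at 47. Of the probe sets higher at 1 h 44 were also higher at 6 h, where independent calls give 1.84, and 53 were higher at both 6 and 24 h, where independent calls give 10.3. At 6 and 24 h 19 probe sets moved in opposite directions. Across probe sets, which are not independent replicates, the log2 changes correlated with r = 0.40 between 24 and 72 h (Spearman 0.44), 0.23 between 1 and 6 h (Spearman 0.07), 0.14 between 6 and 24 h (Spearman 0.05) and −0.14 between 6 and 240 h (Spearman −0.21). Leaving out each array in turn gave 0.34 to 0.40, 0.15 to 0.27, 0.09 to 0.17 and −0.16 to −0.07 for these 4 pairs of times, with jackknife SEs of 0.09, 0.12, 0.09 and 0.09.

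**Figure D4:**
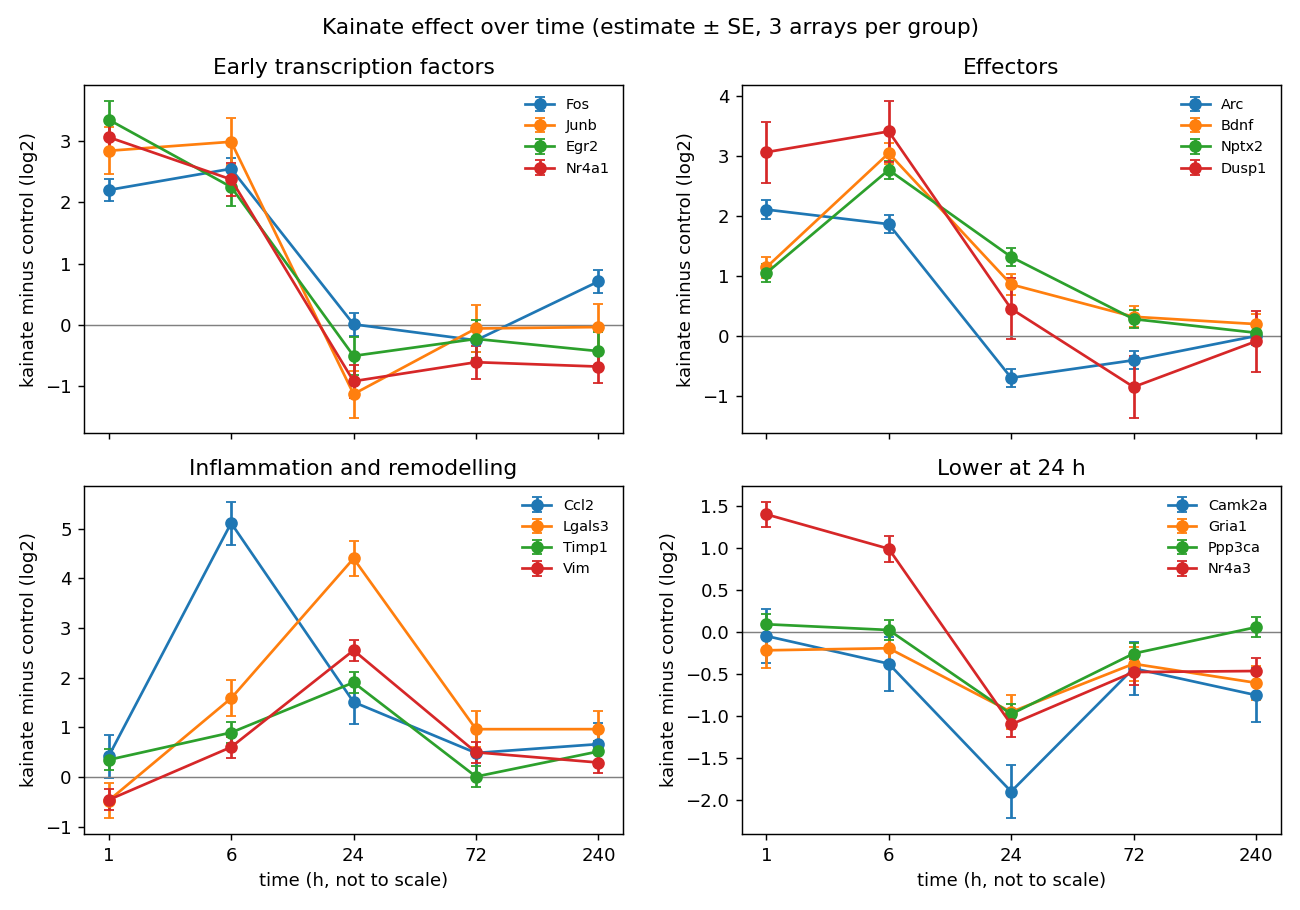
Log2 change after kainate (y axis, kainate minus control) over time (x axis, h, not to scale) for 16 genes in 4 panels, points showing the estimate and bars its SE with 3 arrays per group. Fos and Junb are higher at 1 and 6 h, Ccl2 reaches 5.11 at 6 h, Lgals3 reaches 4.40 at 24 h, and Camk2a, Gria1 and Ppp3ca are lower at 24 h. Each gene is shown by the probe set that stands for it. Other probe sets of Camk2a and Gria1 did not pass at 24 h.

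Control groups were also compared between times. Among the controls 1054 probe sets differed between times by the limma F test, with 2154 at an unadjusted p under 0.05. Controls of 6 and 72 h differed at 8 probe sets and those of 1 and 24 h at 5, whereas the other pairs of times differed at between 260 and 637. Controls of 240 h differed from those of 1 and 24 h, in the same set of arrays, at 352 and 335. Fitted with the arrays of 6 and 72 h alone, 5 probe sets differed among controls, and with the arrays of 1, 24 and 240 h alone 160. With all arrays and array weights 1762 differed. Between the 2 sets of arrays, time and set cannot be told apart in the controls, since each time lies in a single set.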

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

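Tests chosen only after the result was seen were those of the few probe sets at 72 h, of the arrays of 6 and 72 h standing apart, and of the share of neurons, and the regroupings within the 2 sets of arrays.

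The kainate effect differed between times at 418 probe sets by the limma F test. By the probe set that stands for each gene, those passing in opposite directions at different times, with a test of the difference itself, were the following. From 1 to 24 h the log2 effect of Egr1 changed by −2.05, that of Nr4a3 by −2.49, that of Nr4a1 by −3.98 and that of Arc by −2.81. From 6 to 24 h it changed by −1.99 for Idi1, −1.82 for Egr1, −2.09 for Nr4a3, −3.29 for Nr4a1, −2.57 for Arc, −2.08 for Dusp6, −1.32 for Nrn1, −1.59 for Syne1 and −1.11 for Dnajb5. It changed by 2.73 for Dbp and by 1.13 for Clns1a. Other probe sets changed by 2.56 for Txnrd2 from 1 to 24 h and by −1.48 for Ptpn1 from 6 to 24 h, while those standing for these 2 genes did not pass at either time.

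Other splits of the same arrays were counted for each comparison. Within a single time 3 against 3 arrays give 10 splits, too few for a share under 0.05. The real split had 69 probe sets at 1 h against at most 29 in another split, and a simulation without any change gave 37 at 1 h when each probe set had its own spread at each time. It had 249 at 6 h against 1, 713 at 24 h against 2, 3 at 72 h against 0 and 3 at 240 h against 2. In each of the following, 1 of 100 regroupings gave as many as the real one, which was itself. The mean effect had 278 against at most 103, the effect at any time 588 against 414, the differences between times 418 against 35 and the controls 1054 against 118. Chance can be excluded for the mean effect, the effect at any time and the controls. For the differences between times, the regroupings shuffle times among controls as well as among kainate arrays. They ask whether any times differ, not whether the kainate effects differ, and do not decide the latter.

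The regroupings for the differences between times and for the controls mix the arrays of 6 and 72 h with the others. Times were therefore also shuffled within each set of arrays. The differences between times then had 418 against at most 82, with 1 of 100 giving as many, and among controls 2 of 100 gave as many, 1054 for the real one and 1092 for the other. With the arrays of 1, 24 and 240 h alone the differences had 119 against 47 and the controls 160 against 137, each with 1 of 100. Chance can be excluded for the controls in both cases. For the differences between times these regroupings again shuffle the controls too, so they do not decide whether the kainate effects differ. With the arrays of 6 and 72 h alone 281 probe sets differed in effect and 5 of 100 regroupings gave as many, at most 417, but this test decides nothing. In 9 of the other 99 the kainate arrays of each time stayed together, which keeps their difference, and the other 4 of the 5 are among these, while the remaining regroupings gave at most 2. The controls of 6 and 72 h had 5 against 1, with 10 splits, too few for a share under 0.05.

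Few probe sets passed at 72 h. The pooled spread of all times may hide changes there, since with array weights 151 passed in the real split and at most 10 in another. Against it, the arrays of 6 and 72 h alone gave 5 probe sets and those of 72 h alone 0, although at an unadjusted p under 0.05 they gave 812 and 944, against 399 with all arrays. The 72 h effect may be a smaller form of the 24 h effect: over the probe sets called at 24 h its median in the 24 h direction was 0.22, at most 0.11 in other splits and 0.77 at 24 h itself, and 625 of 713 had the same sign. Both stay open as hypotheses.

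The arrays of 6 and 72 h stood apart from the others. A gradual change with elapsed time is argued against, since controls of 6 and 24 h differed at 335 probe sets and those of 6 and 72 h at 8. Separate laboratory processing is a candidate explanation, since the spike-in transcript CreX differed by 0.50 log2 units between the sets (permutation p = 4e-05, two-sided). That permutation shuffles single arrays, whereas each set holds whole times and was seen in these same arrays. Its p therefore overstates the support. RNA quality moved with the sets as well and stays open, with a beta-actin 3 prime to 5 prime log2 ratio of 0.44 ± 0.10 (SD) at 6 and 72 h and 0.68 ± 0.15 at the other times, and a hexokinase ratio of 0.97 ± 0.24 and 1.40 ± 0.32. A biological difference between the times stays open and untested.

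Neuron markers were lower at 24 h. Markers of other cell types did not move alike: the microglia median exceeded the astrocyte median by 0.98 (95% bootstrap interval over list members 0.50 to 2.09). This argues against a lower share of neurons as the only change. The comparison was chosen after both lists had been seen, and its interval measures the spread over genes, not between arrays. The interval therefore overstates the support. The comparison cannot speak against a lower share of neurons together with a change in microglia, which would give the same gap. A bound on the astrocyte list alone had been tried first and decided nothing, its median being −0.31 (−0.53 to 0.04). The outlying array kainate 24 h replicate 3 is argued against as well, since without it the list had a camera adjusted p = 0.000102, and leaving out each of the 6 arrays of 24 h gave an adjusted p = 4.47e-05 to an adjusted p = 0.000908. A lower share of neurons beside a change in microglia, and lower expression within neurons, may contribute and stay open.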

How the results depend on the processing

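Fits with the arrays of 6 and 72 h alone, or of 1, 24 and 240 h alone, were chosen after seeing the data. Of the named genes' values under alternatives 1542 kept their side of the threshold, 265 lost it, 12 gained it and 0 reversed, and of the list values 292 kept it and 38 lost it. The causes were not tested, except that fewer arrays or probe sets entered some fits. Low signal over background limits the genes near the floor.

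With array weights the counts were 633 at 6 h, 543 at 24 h, 151 at 72 h, 923 for any time and 1762 among controls. With the arrays of each time alone they were 31 at 1 h, 274 at 6 h, 256 at 24 h and 0 at 72 and 240 h. With the arrays of 6 and 72 h alone they were 481 at 6 h, 5 at 72 h, 362 for any time and 5 among controls. With those of 1, 24 and 240 h alone they were 43 at 1 h, 343 at 24 h, 0 at 240 h, 50 for the mean, 187 for any time, 119 for differences between times and 160 among controls. At 72 h there were 7 with the floor at the 40th percentile, 10 without the filter and 0 without the trend. At 240 h there were 1 with either other floor, 13 without the filter and 0 with the stricter one. Quantile normalization split the 240 h calls into 3 higher and 1 lower, against 3 and 0. With an estimated correlation 20 list tests passed.

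The replicate block left 57, 239, 695, 0 and 3 probe sets at the 5 times and 281, 488, 312 and 1029 in the tests over times. Whether the numbers pair the arrays is not stated in the labels, and the values do not settle it. Of the same-number correlations 3 of 15 exceeded 0.1, with a range of −0.07 to 0.17, and the own number was highest in 7 of 15.

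Leaving out each array in turn gave 51 to 96 at 1 h, 163 (without kainate 6 h replicate 3) to 279 at 6 h, 338 (without kainate 24 h replicate 3) to 716 at 24 h, 0 to 1 at 72 h and 0 to 19 at 240 h. It gave 212 to 398 for the mean, 431 to 709 for any time, 308 to 473 for differences, 781 to 1069 among controls and 28 to 35 for lists. The Gapdh ratio difference ran from −0.00229 (without control 24 h replicate 1) to 0.0475.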

Other observations

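Chosen only after the result was seen were the exact permutation test of the clock genes, the values of single clock genes, and the values of Hspb1 and Npy. Npy, a neuropeptide of inhibitory neurons, rose by 0.52 at 6 h and 0.77 at 24 h on the log2 scale. The probe set standing for Hspb1, a small heat shock protein, had a log2 change of −0.06 at 24 h and did not pass, while its other 3 probe sets rose by 2.79, 4.11 and 5.28.

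Dbp was lower at 6 h and higher at 24 h, a difference of 2.73 on the log2 scale. A shift of the circadian clock is a candidate explanation, and a test of the other clock genes measured as a set does not decide it. For the difference between the 24 and 6 h effects the set gave camera p = 0.949 and an exact permutation p = 0.57, two-sided. The test had been set to count such a p against a shift, but this was wrong, since the set joins genes that peak at different times of day. Nr1d2, the only gene of the set that passed, differed by 1.57 (limma adjusted p = 0.00436), and Bmal1 differed by −0.74 without passing (limma adjusted p = 0.476). Tef differed by 0.20 (limma adjusted p = 0.780), Nr1d1 by 0.27 (0.662), Hlf by 0.66 (0.658) and Per2 by −0.16 (0.860), and none of these passed. Csnk1d differed by 0.27 (limma adjusted p = 0.665), Bhlhe40 by −0.57 (0.339) and Bhlhe41 by −0.79 (0.111), also without passing.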
